A study of Homo sapiens with 9 samples.

How the data were processed

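Gene expression was measured by poly(A) RNA sequencing in MV4;11 cells, a human acute myeloid leukaemia line that carries a KMT2A fusion, recovered from the bone marrow of engrafted mice. Mice received vehicle, (R)-dHTC1 or (S)-dHTC1, a pair of enantiomers, and 3 mice per group were sequenced, so the series holds 9 libraries in 3 groups. Per the labels' protocols, each compound was given at 50 mg/kg by intraperitoneal injection in 3 doses 12 h apart, marrow was taken 1 h after the last dose, and mouse cells were removed on columns before RNA was extracted. The libraries came from separate mice, and p-values therefore measure the spread between mice that carry the same cell line.

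The deposited table holds raw counts per human gene symbol, one column per mouse, with no normalization. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, STAR 2.7.5a, Picard 2.9.4, SAMtools, HTSeq and DESeq2, and the builds GRCh38 and hg38. The table's name refers to sorted reads with duplicates removed. Removal of reads that share both ends can lower the counts of highly expressed genes relative to the rest. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes were treated as not separable. Each column was tied to its mouse by the sample title. Mice are numbered here 1 to 3 within each group, in the order of their titles, and not by the 2 numbers in the titles. Vehicle mice 1, 2 and 3 have first numbers 1, 2 and 2 and second numbers 2, 0 and 4 in their titles. The table has 59699 rows. The 92 rows that name no gene held 5 counts, 4e-06% of all counts, and were left out. The 130 rows whose symbol occurs more than once were kept as separate rows.

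Total counts per library ranged from 12148258 to 17777592. Of 34547 genes with any count, 15136 passed edgeR's filterByExpr and were tested. Normalization used TMM, and values per mouse are CPM (counts scaled to a common library total) that include the TMM factor. Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) on all 9 libraries in one fit without covariates, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.123. Standard errors of log2 fold changes were taken from the F statistic, and 95% intervals from the fit's degrees of freedom. The 4 results are (R)-dHTC1 against vehicle, (S)-dHTC1 against vehicle, (R)-dHTC1 against (S)-dHTC1, and a test of any difference among the 3 groups.

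The design, the alternatives and 34 gene lists were fixed before the data were examined. The lists cover leukaemic programmes, cell growth, stress, immune signalling and cell types that marrow can hold. Lists with at least 5 tested members, 32 of them, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, were run beside it. Genes named in the text followed a rule. For each comparison it took the 12 largest increases and the 12 largest decreases among genes with an adjusted p below 0.05, a mean of at least 5 CPM over the 9 libraries and no overlap between the groups. It also took MLLT1, MLLT3, CRBN, HOXA9, HOXA10, MEIS1, MYC, MYB, FLT3, BCL2, CDK6, PBX3, JMJD1C and MEF2C in every case, and the 4 members with the smallest p of each list described.

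The gene test was checked on simulated counts for the 15136 genes, with 200 genes changed in the (S)-dHTC1 group alone. Against vehicle it recovered 71% of the 100 genes changed 2-fold and 39% of the 100 changed 1.5-fold, with 11 false calls among 121. Between the enantiomers it recovered 69% and 39%, with 7 false calls among 115. In the comparison of (R)-dHTC1 with vehicle, where nothing had been changed, it made 0 calls. With one list of genes raised in simulated data, camera called that list and 0 of the others. The simulated genes were drawn independently, so this check does not cover lists whose genes move together. In the data the estimated correlation reached 0.93, for the ribosomal protein list with (R)-dHTC1 against vehicle.

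Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or library size alone for scaling, no filter on low counts or a stricter one (at least 5 CPM in 3 libraries), fits on only the groups compared, a block on the first mouse number in the titles, a threshold of 0.01, and each library left out in turn. A fit without vehicle mouse 2 and (S)-dHTC1 mouse 1 was added after the data had been seen. Comparisons that share libraries were set beside 100 simulated data sets with no effect and 100 in which (S)-dHTC1 alone differed, by its measured means, drawn from negative binomial counts with the gene-wise dispersions. Those means include noise between mice, and these data sets had 1109 genes called for (S)-dHTC1 against vehicle on average, where 344 were observed. Within groups, counts of any pair of libraries differed by more than sampling noise, with a chi-square per gene of 2.68 to 20.3, so all 9 were counted as separate mice. Principal components used log2 CPM, with a prior count of 2, of the 1000 genes with the highest variance. Coordinates are from GENCODE release 29 on GRCh38. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.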

Results

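The series measured gene expression in MV4;11 leukaemia cells taken from the marrow of xenografted mice after short treatment with one of a pair of enantiomers. dHTC1 is known as a compound that brings ENL, a chromatin reader with a YEATS domain encoded by MLLT1, to the ubiquitin ligase receptor cereblon, encoded by CRBN. The values here are of RNA and do not show whether ENL protein was lost. Of the 4 mice dosed per group, 3 were sequenced in the vehicle group, in the (R)-dHTC1 group and in the (S)-dHTC1 group. Total counts were between 13002003 and 16411630 in the vehicle libraries, between 12148258 and 17777592 with (R)-dHTC1, and between 12720045 and 13344043 with (S)-dHTC1. The labels do not say which enantiomer was meant as the active one.

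Along the first principal component, 37.2% of the variance, the (S)-dHTC1 mice lay at 24.9, 12.1 and 9.24 and the vehicle mice at -16.8, 5.50 and -13.9. The (R)-dHTC1 mice lay at 1.36, -10.3 and -12.1. Vehicle mouse 2 stood apart on the second component, with a score of -27.6 against -2.13 and 0.707 in the other vehicle mice. Its immediate early genes, which respond within minutes to stimuli and handling, had a median log2 deviation of 0.72 from their mean over the 9 libraries, against -0.36 and -0.27 in the other vehicle mice.

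**Figure D1:**
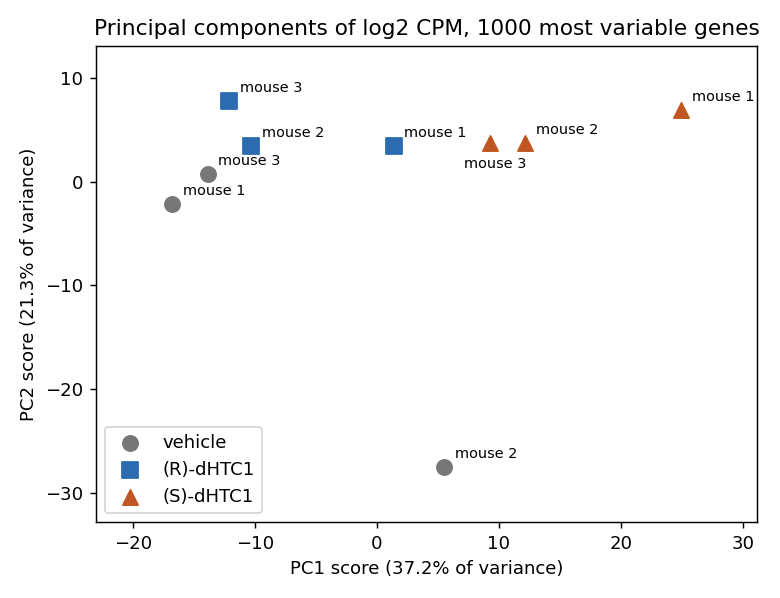
Scores of the 9 libraries on the first and second principal components of log2 CPM, with axes giving the percent of variance and each point being one mouse. Vehicle mouse 2 sits at -27.6 on the second component and (S)-dHTC1 mouse 1 at 24.9 on the first.

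The first comparison asked what (S)-dHTC1 did to the leukaemia cells relative to vehicle. Genes of monocyte and phagocyte function rose with (S)-dHTC1. CHI3L1, a secreted chitinase-like protein of macrophages, went from 18.2 ± 1.42 to 71.4 ± 8.51 CPM (SD, n = 3 each), a log2 fold change of 1.97 ± 0.13 (SE). LSP1, an actin-binding protein of leukocytes, went from 14.2 ± 2.46 to 75.9 ± 14.0 CPM, a log2 fold change of 2.42 ± 0.19. Of 27 known targets of KMT2A fusions and ENL, 4 fell, among them MYB, a transcription factor of blood progenitors, from 540.0 ± 79.0 to 314.5 ± 12.9 CPM, and HOXA9, a homeobox gene kept on by KMT2A fusions, from 43.0 ± 8.40 to 24.2 ± 1.38 CPM.

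In the list of monocyte and macrophage maturation genes, 15 of 33 measured members rose, 0 fell and 18 did not pass the test, and adjusted over the list alone 22 rose and 1 fell. The median log2 fold change was 0.50 (camera adjusted p = 5.28e-28), and the call held with adjusted p = 0.0347 with an estimated correlation and with fry (adjusted p = 0.00408). The integrin subunits ITGAM and ITGAX, which form the CD11b and CD11c receptors, rose by log2 fold changes of 1.10 ± 0.10 and 1.53 ± 0.17 (edgeR adjusted p = 0.000272 and 0.00139). CYBB, the catalytic subunit of the oxidase behind the oxidative burst of phagocytes, rose by 1.07 ± 0.13 (edgeR adjusted p = 0.00172). In each of the 3 (S)-dHTC1 mice the list's median deviation from its mean over the 9 libraries, 0.53, 0.26 and 0.33, lay above all vehicle values, which were -0.27, -0.05 and -0.27.

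**Figure D2:**
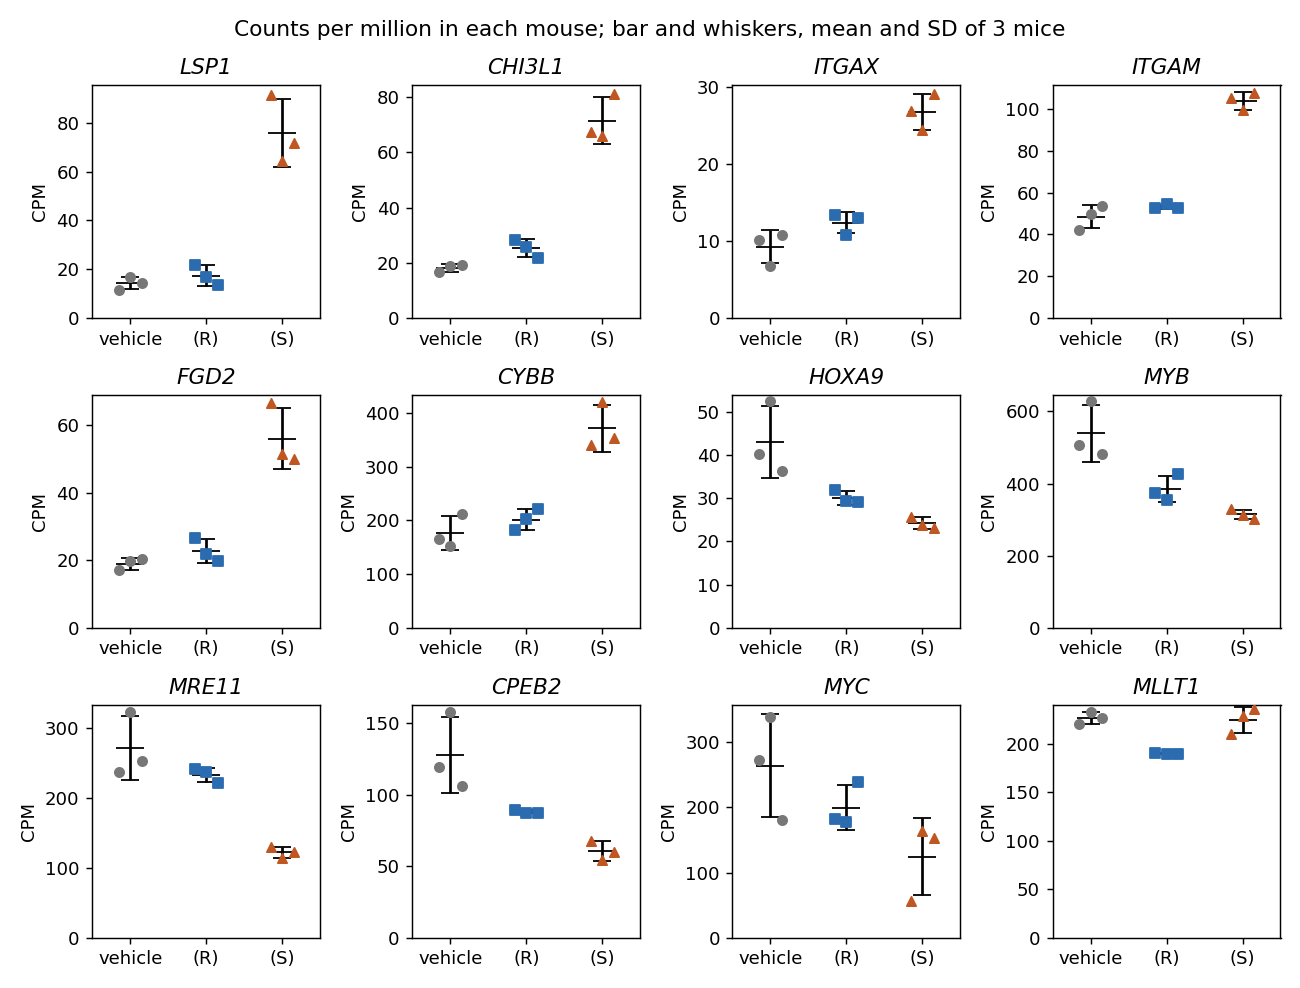
CPM of 12 genes in each mouse by group, with symbols for single mice and bars for the mean and SD of 3 mice. ITGAM, FGD2, CYBB, LSP1, CHI3L1 and ITGAX are higher in every (S)-dHTC1 mouse than in every vehicle and (R)-dHTC1 mouse, and HOXA9, MYB, MRE11 and CPEB2 are lower.

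Of 27 measured members of a list of known targets of KMT2A fusions and ENL, 4 fell, 0 rose and 23 did not pass the test with (S)-dHTC1, and adjusted over the list alone 8 fell and 2 rose. Fold changes were above 0 in 11 and below 0 in 16. The 4 were CPEB2 (log2 fold change -1.07 ± 0.13), MYB (-0.78 ± 0.11), HOXA9 (-0.83 ± 0.13) and HOXA10 (-0.72 ± 0.14), with edgeR adjusted p = 0.00219, 0.00292, 0.00704 and 0.0213. Without 1 library at a time the edgeR adjusted p of HOXA10 ran from 0.0127 to 0.0959. The HOXA10 call was lost without vehicle mouse 1 (-0.71), vehicle mouse 3 (-0.70) or (S)-dHTC1 mouse 2 (-0.59), and HOXA9 and HOXA10 overlap in the annotation, so their counts are not fully separable. The list's median was -0.21 (camera adjusted p = 2.66e-05), a call not kept at adjusted p = 0.461 with an estimated correlation. It was -0.10 without vehicle mouse 2 and -0.12 without (S)-dHTC1 mouse 2. The list's median deviation was 0.13, 0.22 and 0.02 in the vehicle mice and 0.03, -0.12 and -0.14 in the (S)-dHTC1 mice. The groups thus overlapped, with (S)-dHTC1 mouse 1 above vehicle mouse 3. In the fit without both vehicle mouse 2 and (S)-dHTC1 mouse 1, 9 of the 27 were lower and 0 higher. The stem and progenitor list had 0 of 11 members past the test and a median of -0.15 (camera adjusted p = 0.546), which ran from -0.19 to 0.11 over the 9 fits without 1 library and was above 0 without vehicle mouse 2. MEIS1, the cofactor of HOXA9, did not pass the test at -0.43 (edgeR adjusted p = 0.0812) but passed without (S)-dHTC1 mouse 1 (-0.55), with DESeq2 and without a filter on low counts. It also passed without both vehicle mouse 2 and (S)-dHTC1 mouse 1 (-0.57, edgeR adjusted p = 0.00769). MYC did not pass at -1.08 (95% interval -1.77 to -0.39, edgeR adjusted p = 0.102) except without a filter on low counts. MYC had 56.3, 164.1 and 153.2 CPM in the (S)-dHTC1 mice and 272.8, 338.9 and 180.6 CPM in the vehicle mice.

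MLLT1 itself differed by -0.01 (95% interval -0.17 to 0.14) and CRBN by 0.00 (-0.22 to 0.21) between (S)-dHTC1 and vehicle, and neither passed the test. RNA values of MLLT1 and CRBN do not measure the ENL and cereblon proteins. Among called genes with a mean of at least 5 CPM, the largest increase was that of THBS1, a secreted matrix protein, at 2.91 ± 0.66 (edgeR adjusted p = 0.0414), a call lost without vehicle mouse 1 or 3, (R)-dHTC1 mouse 3 or (S)-dHTC1 mouse 1 or 2 (values of 2.43 to 4.19 over the 9 fits without 1 library). JAML, an adhesion molecule of leukocytes, rose by 2.46 ± 0.35 and kept its call in all 9 such fits. Among the largest decreases were those of MRE11, a nuclease of DNA break repair, which fell by 1.15 on the log2 scale from 271.3 ± 45.8 to 122.1 ± 8.11 CPM, HMX2, a homeobox gene, which fell by 1.31, and CDKN1B, a cell cycle inhibitor, which fell by 0.99. Of the 26 measured subunits of the super elongation complex, the DOT1L complex and the menin complex, 0 changed by edgeR, also when adjusted over the list alone, and the list median was -0.01.

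Coordinates of the genes discussed most are given on GRCh38 as annotated gene spans, all of them of protein-coding genes. MLLT1 lies on chromosome 19 from 6210379 to 6279948, MYB on chromosome 6 from 135181315 to 135219173, HOXA9 on chromosome 7 from 27162435 to 27175180 and HOXA10 on chromosome 7 from 27170591 to 27180261. ITGAM and ITGAX are neighbours on chromosome 16, from 31259967 to 31332892 and from 31355134 to 31382997. LSP1 lies on chromosome 11 from 1852970 to 1892267, CHI3L1 on chromosome 1 from 203178931 to 203186749, MRE11 on chromosome 11 from 94415578 to 94493908, and CPEB2 on chromosome 4 from 15002674 to 15070153.

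Interferon-stimulated genes were higher with (S)-dHTC1, mostly in one mouse. In that list 4 of 26 members rose (IFI6, MX2, MX1 and OAS1), 0 fell and 22 did not pass the test, with 16 rising when adjusted over the list alone. The median was 0.66 (camera adjusted p = 1.23e-09, but adjusted p = 0.461 with an estimated correlation). The list's median deviation was 0.89 in (S)-dHTC1 mouse 1 against 0.06 and -0.01 in mice 2 and 3, and without mouse 1 the median fell to 0.28. IFI6 rose by 1.52 ± 0.20 and kept its call in each of the 9 fits that left out a library, while MX1 and OAS1 each kept it in 1, the fit without (S)-dHTC1 mouse 3, and MX2 lost it without vehicle mouse 1 (1.33). CIITA, the master regulator of MHC class II genes, rose by 1.35 and was the 1 called member of 10 in that list, whose median was 0.43 (camera adjusted p = 0.00166, adjusted p = 0.461 with an estimated correlation).

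Lists of proliferation and growth genes had medians below 0 with (S)-dHTC1 although 0 of their members passed edgeR's test one by one. The medians were -0.21 for S phase genes, -0.20 for G2 and mitosis genes and -0.21 for MYC-responsive ribosome biogenesis genes (camera adjusted p = 1.24e-08, 8.38e-07 and 1.91e-09). Each was at adjusted p = 0.461 with an estimated correlation. Without both vehicle mouse 2 and (S)-dHTC1 mouse 1, single members did pass as lower and 0 as higher. They were 7 of 34 S phase, 2 of 31 G2 and mitosis and 4 of 35 ribosome biogenesis genes. The ribosome biogenesis median was -0.08 without (S)-dHTC1 mouse 1, in which the list deviated by -0.32, against 0.13 and 0.02 in the other (S)-dHTC1 mice and 0.22, 0.13 and 0.15 in the vehicle mice. The heat shock list had a median of -0.31 with 0 of 17 members past the test and 6 lower when adjusted over the list alone (camera adjusted p = 3.11e-06, adjusted p = 0.461 with an estimated correlation). Its median deviations were 0.29, -0.24 and 0.38 in the vehicle mice and -0.50, -0.10 and -0.10 with (S)-dHTC1, so that vehicle mouse 2 lay below 2 of the (S)-dHTC1 mice. The heat shock median was -0.52 without vehicle mouse 2 and -0.48 without (S)-dHTC1 mouse 3. Of the 17 heat shock genes, 10 were lower and 0 higher without both vehicle mouse 2 and (S)-dHTC1 mouse 1. Camera also called the respiratory chain (-0.15), proteasome (-0.13), endoplasmic reticulum chaperone (-0.15) and sterol synthesis (-0.12) lists lower and the NF-kappaB (0.33) and histone (0.54) lists higher, each at adjusted p = 0.461 with an estimated correlation except sterol synthesis at adjusted p = 0.624 with an estimated correlation. The respiratory chain median was -0.09 without vehicle mouse 2 and the proteasome median -0.07 without (S)-dHTC1 mouse 1. The chaperone call was lost without (S)-dHTC1 mouse 1 (-0.06), the NF-kappaB call without vehicle mouse 3 or (S)-dHTC1 mouse 3 (0.24 to 0.62 over the 9 fits without 1 library) and the histone call without (S)-dHTC1 mouse 1 or 3 (0.28 to 0.71). The NF-kappaB median was 0.62 without vehicle mouse 2 and 0.55 without (S)-dHTC1 mouse 1, and the histone median 0.28 without (S)-dHTC1 mouse 1. The histone list holds replication-dependent histones, mostly without poly(A), and was fixed beforehand as a sign of poly(A) selection. Whether that selection differed between libraries was not tested. The sterol synthesis call was lost without vehicle mouse 1 or 3 or (S)-dHTC1 mouse 1 (-0.21 to -0.01), and its median was -0.04 without vehicle mouse 1, -0.01 without (S)-dHTC1 mouse 1, and -0.20, -0.21 and -0.19 without vehicle mouse 2 and (S)-dHTC1 mice 2 and 3.

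**Figure D3:**
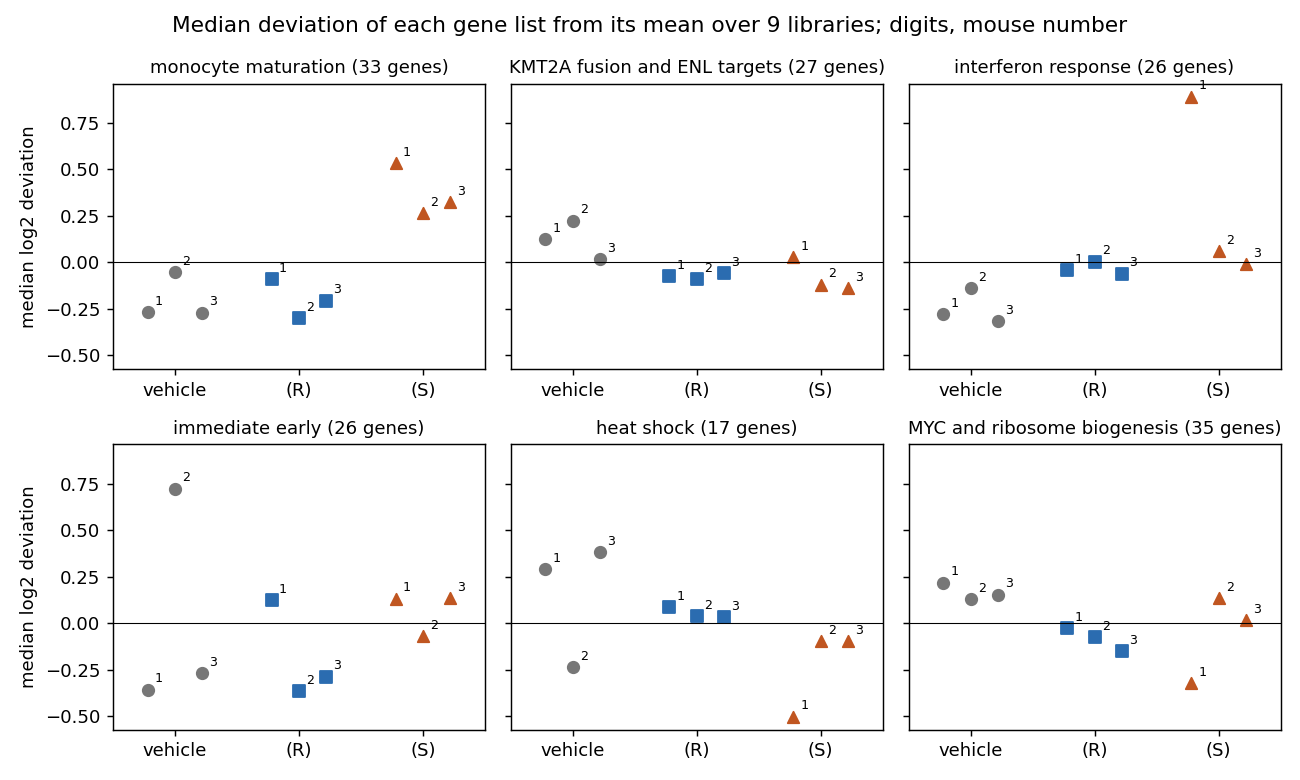
Median log2 deviation of 6 gene lists from their own mean over the 9 libraries, one symbol per mouse, by group, with digits for mouse numbers. The monocyte list lies at 0.26 or more in all (S)-dHTC1 mice, the interferon list reaches 0.89 in (S)-dHTC1 mouse 1 alone, and the immediate early list reaches 0.72 in vehicle mouse 2 alone.

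Across all 15136 genes, 344 passed edgeR's test between (S)-dHTC1 and vehicle, of which 289 rose and 55 fell, 130 and 13 of them by at least 2-fold. In all 344 the 3 mice of one group lay outside the range of the other, as did 20.9% of all genes where chance gives 10%. That share was 22.6% for (R)-dHTC1 against vehicle, where edgeR called 0 genes, so it does not set (S)-dHTC1 apart. Of the 24 genes with the largest changes, 15 kept their call whichever library was left out. The count moved to 872 without vehicle mouse 2, 99 without vehicle mouse 1, 164 without vehicle mouse 3, 213 without (R)-dHTC1 mouse 3, and 163 and 215 without (S)-dHTC1 mice 1 and 2, and was 771 with DESeq2. Without both vehicle mouse 2 and (S)-dHTC1 mouse 1 it was 914, with 304 of the 344 among them, and the monocyte list had 18 genes higher and 0 lower.

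The second comparison set (R)-dHTC1, the mirror image compound at the same dose and times, against vehicle. No gene passed edgeR's test after adjustment, and the smallest adjusted p was 0.0634, while 1954 genes had an unadjusted p below 0.05 where 757 would be so by chance. That count of 1954 was 1402 and 960 without (R)-dHTC1 mice 2 and 3, 2437 without (S)-dHTC1 mouse 1, and 1062 with the block on the first mouse number. DESeq2 called 189 genes, 61 higher and 128 lower, and limma-voom 0. Of the leukaemia genes chosen beforehand, MYB, HOXA9 and CDK6 lay below vehicle without passing edgeR's test, with MYB at a log2 fold change of -0.49 ± 0.11 (edgeR adjusted p = 0.140), HOXA9 at -0.51 ± 0.13 (edgeR adjusted p = 0.201) and CDK6, a cell cycle kinase, at -0.36 ± 0.08 (edgeR adjusted p = 0.155), while JMJD1C, a chromatin protein, was at 0.06 (edgeR adjusted p = 0.798). MYB, HOXA9 and CDK6 passed with DESeq2 and without a filter on low counts, and MYB (-0.37) and CDK6 (-0.42) without both vehicle mouse 2 and (S)-dHTC1 mouse 1. MLLT1 had 190.0 ± 0.727 CPM with (R)-dHTC1 and 226.8 ± 6.15 CPM with vehicle, a log2 difference of -0.26 (95% interval -0.41 to -0.10, edgeR adjusted p = 0.228, DESeq2 adjusted p = 0.0328), and CRBN differed by 0.06 (-0.16 to 0.27).

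The KMT2A fusion and ENL target list had a median of -0.26 with (R)-dHTC1, with 0 of 27 members past the test and 6 lower when adjusted over the list alone (camera adjusted p = 5.57e-07, adjusted p = 0.266 with an estimated correlation). Fold changes were above 0 in 6 of the 27, and the median was -0.17 without vehicle mouse 2. The list's median deviation was -0.07, -0.09 and -0.06 in the (R)-dHTC1 mice, below the vehicle values of 0.13, 0.22 and 0.02. Of the 27, 5 were lower and 0 higher without both vehicle mouse 2 and (S)-dHTC1 mouse 1. The list of cereblon ligase subunits and proteins known to be degraded through cereblon had a median of -0.14, with 2 of 15 members lower when adjusted over the list alone (camera adjusted p = 0.00134, adjusted p = 0.253 with an estimated correlation, fry adjusted p = 0.00243). Its lowest members by p were the zinc finger genes ZBTB16 (-0.77 ± 0.14) and IKZF1 (-0.47 ± 0.10), both at edgeR adjusted p = 0.140, which passed with DESeq2, without a filter on low counts and without both vehicle mouse 2 and (S)-dHTC1 mouse 1. These RNA values do not show whether the proteins were degraded. MYC-responsive ribosome biogenesis genes had a median of -0.23 (camera adjusted p = 6.1e-13, adjusted p = 0.794 with an estimated correlation). Of these 35 genes, 11 were lower and 0 higher without both vehicle mouse 2 and (S)-dHTC1 mouse 1. The monocyte maturation list had a median of 0.02 and 0 members past the test, also when adjusted over the list alone.

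Camera also called the interferon list (median 0.21) and the NF-kappaB list (0.25) higher, and the ribosomal protein (-0.14), respiratory chain (-0.10), proteasome (-0.10) and stem and progenitor (-0.27) lists lower. In that order the camera adjusted p were 0.00595, 0.0413, 7.63e-11, 6e-05, 0.000101 and 0.00595. None of these calls was kept with an estimated correlation, at adjusted p = 0.794 for the NF-kappaB and stem and progenitor lists and adjusted p = 0.899 for the 4 others. The NF-kappaB call was lost without vehicle mouse 1 or 3 or (R)-dHTC1 mouse 1 (medians of 0.05 to 0.41 over the 9 fits), and the stem and progenitor call without vehicle mouse 2 (-0.45 to -0.12). The NF-kappaB median was 0.05 and 0.41 without (R)-dHTC1 mice 1 and 2, and the stem and progenitor median -0.13 without vehicle mouse 2 and -0.45 and -0.12 without (R)-dHTC1 mice 1 and 3. The ribosomal protein median was -0.06 and -0.22 without vehicle mice 2 and 3, the respiratory chain median -0.06 without vehicle mouse 2, and the proteasome median -0.14 without vehicle mouse 3 and -0.15 without (R)-dHTC1 mouse 1. In all, camera called 9 of the 32 lists with (R)-dHTC1, 2 higher and 7 lower, and 0 of them with an estimated correlation. The gene count was 0 in each fit without 1 library, but 334, with 104 higher, in the fit without both vehicle mouse 2 and (S)-dHTC1 mouse 1, and 401 without a filter on low counts.

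The third comparison tested the enantiomers against each other at matched dose and time. The genes of monocyte maturation were lower with (R)-dHTC1 than with (S)-dHTC1. In that list 17 of 33 members were lower, 0 were higher and 16 did not pass the test, and 24 were lower when adjusted over the list alone. The median was -0.51 (camera adjusted p = 2.12e-30), held at adjusted p = 0.0218 with an estimated correlation and with fry (adjusted p = 0.00334). ITGAM, at 53.3 ± 1.01 CPM with (R)-dHTC1 and 104.1 ± 4.23 CPM with (S)-dHTC1, differed by -0.97 ± 0.10, and CD14, the monocyte co-receptor of endotoxin, by -2.22, both with a call in each fit without 1 library. CD14 was low, at 0.49 to 1.29 CPM with (R)-dHTC1 and 3.38 to 5.09 CPM with (S)-dHTC1. NCF1, a subunit of the phagocyte oxidase, differed by -1.42, but near-identical pseudogene copies make its counts uncertain, and its call was lost without (R)-dHTC1 mouse 2 or 3 (values of -1.56 to -1.25 over the 9 fits).

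LSP1 (-2.12 ± 0.19), CHI3L1 (-1.50 ± 0.12), CIITA (-1.44 ± 0.18) and FGD2 (-1.30), an activator of the GTPase CDC42, were lower with (R)-dHTC1, with edgeR adjusted p = 0.000429, 0.000429, 0.00383 and 0.00179. MRE11 was higher with (R)-dHTC1 by 0.93 ± 0.11 (edgeR adjusted p = 0.00239). ZBTB16 and IKZF1 were lower with (R)-dHTC1 than with (S)-dHTC1, by -0.66 ± 0.14 and -0.43 ± 0.10 (edgeR adjusted p = 0.0315 and 0.0426), the 2 called of 15 members in the list of cereblon ligase subunits and substrates. The ZBTB16 call was lost without (R)-dHTC1 mouse 2 (-0.71) or 3 (-0.52) or (S)-dHTC1 mouse 2 (-0.61) or 3 (-0.59). The IKZF1 call was lost without vehicle mouse 1 (-0.43), (R)-dHTC1 mouse 2 (-0.41) or 3 (-0.39) or (S)-dHTC1 mouse 1 (-0.34), 2 (-0.47) or 3 (-0.49). That list as a whole had a median of -0.02 (camera adjusted p = 0.185, fry adjusted p = 0.0241). RNA values of ZBTB16 and IKZF1 do not show whether their proteins were degraded.

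Camera called 9 of the 32 lists between the enantiomers. Besides the monocyte and sterol synthesis lists these were the S phase (median 0.16), G2 and mitosis (0.11) and heat shock (0.33) lists, higher with (R)-dHTC1, and the ribosomal protein (-0.12), granulocyte (-0.23), interferon (-0.32) and MHC class II (-0.09) lists, lower. The ribosomal protein list was at adjusted p = 0.765 with an estimated correlation and the 6 others at adjusted p = 0.636 with an estimated correlation. The interferon call was lost without (S)-dHTC1 mouse 1 (-0.02), the granulocyte call without (S)-dHTC1 mouse 2 or 3 (-0.47 to -0.19 over the 9 fits without 1 library) and the MHC class II call without (R)-dHTC1 mouse 3 (a median of -0.0035). The granulocyte median was -0.47 without (S)-dHTC1 mouse 1, and the MHC class II median -0.31 without (R)-dHTC1 mouse 1 and -0.16 without (R)-dHTC1 mouse 2 or any 1 (S)-dHTC1 mouse. The heat shock median was 0.20 without (R)-dHTC1 mouse 1 and 0.21 without (S)-dHTC1 mouse 1, the G2 and mitosis median 0.06 without (R)-dHTC1 mouse 3, and the ribosomal protein median -0.18 without (R)-dHTC1 mouse 2.

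Over all 9 libraries the enantiomers were not shown to differ in the known targets of KMT2A fusions and ENL. The KMT2A fusion and ENL target list had a median of -0.01 between them, with 0 of 27 members past the test and 1 higher when adjusted over the list alone (camera adjusted p = 0.971). Without both vehicle mouse 2 and (S)-dHTC1 mouse 1, 4 of the 27 were higher and 2 lower with (R)-dHTC1. Among the 4 were HOXA9 (0.36, edgeR adjusted p = 0.0419) and MYB (0.32, edgeR adjusted p = 0.0260). The 95% intervals of the differences, not adjusted over genes, leave room for effects. They lay above 0 for HOXA9 (0.02 to 0.60), HOXA10 (0.06 to 0.69) and MYB (0.06 to 0.52). Those of MYC (-0.01 to 1.37) and MEIS1 (-0.09 to 0.42) included 0. All are in log2 units with (R)-dHTC1 above (S)-dHTC1 where positive. MLLT1 was at -0.24 (95% interval -0.40 to -0.09, edgeR adjusted p = 0.0973, DESeq2 adjusted p = 0.0213). Without a filter on low counts, MYC and MYB passed. Without vehicle mouse 2 alone, MLLT1 (-0.25) and MYB (0.28) passed. MLLT1 (-0.29) also passed without both vehicle mouse 2 and (S)-dHTC1 mouse 1. Over all genes, the interval lay within 2-fold either way for 80.2%.

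Between the enantiomers 396 of 15136 genes passed edgeR's test, 79 higher and 317 lower with (R)-dHTC1, and with library size alone as scaling 230 did, of which 75 were higher (32.6% in place of 19.9%). The count was 18 and 16 without (R)-dHTC1 mice 2 and 3, 76, 110 and 222 without (S)-dHTC1 mice 1, 2 and 3, 246 without vehicle mouse 1 or 3, and 1093 without vehicle mouse 2. Of the 24 largest changes, 5 kept their call whichever library was left out (LSP1, CHI3L1, CIITA, FGD2 and MRE11). Without both vehicle mouse 2 and (S)-dHTC1 mouse 1 the count was 1194.

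The genes that set (S)-dHTC1 apart from vehicle also set it apart from (R)-dHTC1 in many cases. Higher with (S)-dHTC1 in both comparisons were 149 genes, where independent lists of 289 and 317 would share 6.05, and lower in both were 17, where 0.287 would be shared. Both comparisons use the same (S)-dHTC1 libraries, so the lists are not independent. Simulated data in which (S)-dHTC1 alone differed gave 667.3 such genes on average (598 to 746), with 1109 genes called for (S)-dHTC1 against vehicle on average in place of 344. The sum of 166 moved to 460 without vehicle mouse 2, to 66 and 92 without vehicle mice 1 and 3, to 15 and 16 without (R)-dHTC1 mice 2 and 3, and to 45 and 75 without (S)-dHTC1 mice 1 and 2.

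Across genes, the log2 fold changes of the enantiomers against vehicle correlated with a Pearson's r of 0.47 and a Spearman's rho of 0.42, where genes are not independent replicates. Both use the same vehicle libraries. Simulated data gave an r of 0.50 on average (0.47 to 0.53) with no effect and of 0.30 (0.27 to 0.34) where (S)-dHTC1 alone differed, so the observed r lay within the first range and above the second. The observed r was 0.60 and 0.56 without vehicle mice 2 and 3 and 0.32 without (R)-dHTC1 mouse 1. The covariance was 0.0545 against a simulated 0.0309 (0.0283 to 0.0346) with no effect, a difference of 0.0236, and 0.0316 (0.0277 to 0.0357) where (S)-dHTC1 alone differed. No gene was called the same way in both comparisons by edgeR (26 by DESeq2), with 0.04 on average in simulated data with no effect and 0.18 where (S)-dHTC1 alone differed.

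**Figure D4:**
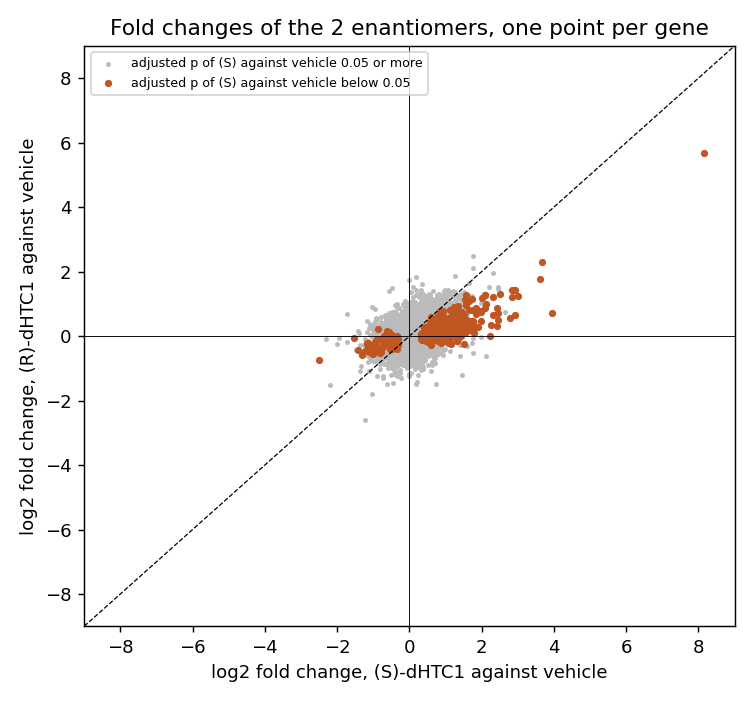
Log2 fold change of each of 15136 genes with (R)-dHTC1 against vehicle (vertical) and with (S)-dHTC1 against vehicle (horizontal), with the 344 genes that passed edgeR's test for (S)-dHTC1 in orange and equality as a dashed line. Of the 344 genes, 294 (85.5%) had the same sign with both compounds, against 66% of all genes. Simulated data in which (S)-dHTC1 alone differed gave 70.3% on average (66.8% to 73.1%), with 1109 genes called for (S)-dHTC1. Simulated data with no effect gave 94.9% (0% to 100%) over the data sets with a called gene, with 0.37 genes called on average over all 100. These shares do not decide whether (R)-dHTC1 acted.

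The test of any difference among the 3 groups called 404 genes by edgeR and 1178 by DESeq2. It called 1113 without vehicle mouse 2, 176 and 207 without vehicle mice 1 and 3, 147 and 133 without (R)-dHTC1 mice 2 and 3, and 166, 171 and 245 without (S)-dHTC1 mice 1, 2 and 3. Without both vehicle mouse 2 and (S)-dHTC1 mouse 1 it called 1484.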

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

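With 3 mice per group, at this depth, 39% of simulated 1.5-fold changes were recovered between (S)-dHTC1 and vehicle, so a gene that did not pass the test is not shown to be unchanged. The fit without both vehicle mouse 2 and (S)-dHTC1 mouse 1 was chosen after the data had been seen. The causes of the shifts below were not tested, except that a stricter threshold leaves fewer genes by construction. DESeq2 called 189 genes for (R)-dHTC1 against vehicle, 771 for (S)-dHTC1 against vehicle, 859 between the enantiomers and 1178 among the groups, with 26 called the same way for both enantiomers and 361 called for (S)-dHTC1 against both other groups. Without a filter on low counts these were 401, 1085, 1162, 1737, 98 and 498, and 15 lists passed between the enantiomers. With library size alone, 230 genes passed between the enantiomers. Fits on only the groups compared gave 182 for (S)-dHTC1 against vehicle and 640 between the enantiomers. At a threshold of 0.01 the counts were 106 for (S)-dHTC1 against vehicle, 35 between the enantiomers and 92 among the groups.

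With a replicate block on the first mouse number, 164 genes passed for (S)-dHTC1 against vehicle, 128 between the enantiomers and 183 among the groups, with 70 called for (S)-dHTC1 against both other groups. Mice with the same number did not deviate together (correlations of -0.17 to 0.10 over 9 pairs, -0.26 to 0.22 over the 18 others), so the number was not taken as a pairing.

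Leaving out each mouse in turn gave 99 to 872 genes for (S)-dHTC1 against vehicle, 16 to 1093 between the enantiomers, 133 to 1113 among the groups, 15 to 460 called for (S)-dHTC1 against both other groups, a fold change correlation of 0.32 to 0.60, and 9 to 15 lists between the enantiomers, while (R)-dHTC1 against vehicle stayed at 0. Without both vehicle mouse 2 and (S)-dHTC1 mouse 1, the counts were 334 for (R)-dHTC1 against vehicle, 914 for (S)-dHTC1 against vehicle, 1194 between the enantiomers, 1484 among the groups, 82 for both enantiomers and 487 for (S)-dHTC1 against both other groups, with a correlation of 0.57. With an estimated correlation, camera called 0 lists for (R)-dHTC1 against vehicle, 1 for (S)-dHTC1 against vehicle and 1 between the enantiomers, and fry called 1, 1 and 2.

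A pair of lists was called in the direction opposite to that over all libraries, each without vehicle mouse 2 and each without both libraries. The immediate early list with (R)-dHTC1 went from a median of -0.35, not called, to 0.368 without vehicle mouse 2 and 0.372 without both (camera adjusted p = 0.0192 and 0.00822), and it was called lower without vehicle mouse 1 or 3 or (R)-dHTC1 mouse 1 (medians of -0.46, -0.51 and -0.576). The ribosomal protein list with (S)-dHTC1 went from -0.02, not called, to 0.0726 and 0.0896 (camera adjusted p = 0.0316 and 0.00483), and it was called lower without vehicle mouse 1 or 3 or (S)-dHTC1 mouse 3 (-0.06, -0.0849 and -0.06) and without a filter on low counts (-0.05). Medians of other lists not called over all libraries also changed sign without 1 library, such as that of the granulocyte list with (R)-dHTC1 (-0.20, and -0.29 to 0.06). No named gene was called in the direction opposite to the value reported, or lost its call with a change of sign, in any alternative. Uncalled named genes did change sign, at most 2 per comparison and alternative, such as CRBN with (R)-dHTC1, at 0.06 and from -0.01 to 0.11 without 1 library. The monocyte list kept its camera call in all 9 fits without 1 library, with a median of 0.44 to 0.62 for (S)-dHTC1 against vehicle and -0.61 to -0.43 between the enantiomers.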

Other observations

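The tests of residual marrow cells, of the monocyte list without vehicle mouse 2, of the immediate early list and of the libraries with fewer counts were chosen after the results they bear on had been seen. Of 19 measured genes of the granulocyte list, 4 rose, 1 fell and 14 did not pass the test with (S)-dHTC1 against vehicle, and adjusted over the list alone 5 rose and 2 fell. The calgranulins S100A8 and S100A9, abundant in mature myeloid cells, rose by 1.45 ± 0.22 and 1.31 ± 0.16, the formyl peptide receptor FPR1 rose by 3.00 and the G-CSF receptor CSF3R rose by 0.61, while CTSG, a protease of the primary granules made by immature cells, fell by 1.18. FPR1 was low, at 0.53 to 1.13 CPM with vehicle and 3.22 to 8.12 CPM with (S)-dHTC1. The CTSG call was lost without vehicle mouse 1 (-1.29), vehicle mouse 3 (-1.28), (R)-dHTC1 mouse 3 (-1.20) or (S)-dHTC1 mice 1 (-0.90) and 2 (-1.28). As a list they did not pass, with a median of 0.02 (camera adjusted p = 0.0591), and medians ran from -0.14 to 0.24 over the 9 fits without 1 library. The list passed as higher without vehicle mouse 2 (0.23), (R)-dHTC1 mouse 1 (0.01) or 2 (0.02) or (S)-dHTC1 mouse 1 (0.24), at the lowest with camera adjusted p = 0.00014. Without both vehicle mouse 2 and (S)-dHTC1 mouse 1 its median was 0.40 (camera adjusted p = 1e-09), with 9 genes higher and 1 lower. Over all 9 libraries the list was at camera adjusted p = 0.671 with an estimated correlation. The S100A8, S100A9 and FPR1 calls held in all 9 fits without 1 library, and the CSF3R call was lost without vehicle mouse 1 or 3 (0.52 to 0.77 over the 9). S100A8, S100A9, FPR1 and CSF3R were named after their values were seen.

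Single genes of other lists also rose with (S)-dHTC1: the drug exporter ABCC1 by 0.48 and the ferritin heavy chain gene FTH1 by 0.63, 2 of 18 genes of the NRF2 antioxidant list, the cytokine signalling inhibitor SOCS1 by 1.17, 1 of 17 in the FLT3 and STAT5 list, and the death receptor gene TNFRSF10B by 0.46, 1 of 21 p53 targets. The ABCC1 call held in all 9 fits without 1 library. Over those fits FTH1 (0.56 to 0.75) lost its call without vehicle mouse 1 or 3 or (S)-dHTC1 mouse 1 or 3, and TNFRSF10B (0.41 to 0.52) without vehicle mouse 1 or 3, (R)-dHTC1 mouse 3 or (S)-dHTC1 mouse 1 or 2. SOCS1 (1.03 to 1.31) lost it without vehicle mouse 1 or 3, (R)-dHTC1 mouse 3 or any 1 (S)-dHTC1 mouse. Among genes listed as markers of other marrow cells, CD22, listed for B cells, rose by 3.67 at 1.30 CPM with (S)-dHTC1. The CD22 call was lost without vehicle mouse 1 or (S)-dHTC1 mouse 1 (3.20 to 4.76). PECAM1, listed for endothelium but at 328.4 CPM already with vehicle, rose by 0.45, a call kept without vehicle mouse 2 alone (0.35 to 0.57). The B cell, T and NK cell, stromal and megakaryocyte lists did not pass (camera adjusted p = 0.0700, 0.457, 0.615 and 0.0934), but the B cell list passed as higher without (S)-dHTC1 mouse 2 (median 0.55, camera adjusted p = 0.0207) and the megakaryocyte list without vehicle mouse 2 (median 0.63, camera adjusted p = 0.0316). These genes were named after their values were seen. Between the enantiomers, the sterol synthesis gene MVK was higher with (R)-dHTC1 by 0.76, the 1 called of 24 members of a list with a median of 0.22 (camera adjusted p = 0.000156, adjusted p = 0.636 with an estimated correlation). The list median was 0.12 without (S)-dHTC1 mouse 1 and 0.34 without (S)-dHTC1 mouse 2. The MVK call was lost without vehicle mouse 3, (R)-dHTC1 mouse 2 or 3 or (S)-dHTC1 mouse 1 or 2 (0.65 to 0.92).

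The count of 404 genes among the groups was reached by 1 of 100 drawn splits of the 9 libraries into 3 groups of 3, the real one. Chance is therefore an unlikely source of that count, though 1 of 100 is the smallest share such a draw can give. The highest other split gave 207 genes and kept the 3 (S)-dHTC1 mice together. For (S)-dHTC1 against vehicle and for the enantiomers, 1 of 10 splits, the real one, gave 344 and 396 genes and the highest other 0, and for (R)-dHTC1 against vehicle all 10 splits gave 0. A set of 10 splits is too few for a share under 0.05.

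The rise of the monocyte maturation list with (S)-dHTC1 is the pattern most worth following up. Residual erythroid cells or granulocytes would bring haemoglobin and granule transcripts, but HBA1, HBA2, HBB, LTF, CAMP and LCN2 together reached at most 0.455 CPM in an (S)-dHTC1 library, with the limit that mouse reads align to human genes only in part. Residual monocytes or macrophages, which that sum does not cover, stay open. Of their transcripts, C1QA, C1QB, C1QC, CD163, FCN1 and VCAN together were at 2.68 ± 0.608 CPM with vehicle and 4.16 ± 0.708 CPM with (S)-dHTC1, and at most 8.39 CPM in an (R)-dHTC1 library. Single mice overlapped, with 3.38 CPM in vehicle mouse 1 and 3.36 CPM in (S)-dHTC1 mouse 1. How well mouse reads of these genes align is not known. Vehicle mouse 2 lay nearest the (S)-dHTC1 mice on this list, at -0.05 against -0.27 and -0.27 in the other vehicle mice. Its level therefore did not produce the rise, and the higher median without it, 0.62, could be foreseen and is no further test. After removal of the trend of fold change on GC content and transcript length the list's median was 0.47, against 0.50 before, which argues against that trend as the whole cause. A hypothesis that also stays open is that (S)-dHTC1 may push these leukaemia cells towards a more mature monocytic state, untested here beyond expression.

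Several counts moved by over 1.5 times without vehicle mouse 2. Its immediate early list deviated by 0.723, against at most 0.136 in the 8 other libraries and above all 10000 random lists of the same size and expression. The random genes were drawn singly, while immediate early genes move together (estimated correlation of 0.562 with (S)-dHTC1 against vehicle). Their rank among random lists therefore does not measure how unusual the deviation is. A handling or stress response in vehicle mouse 2 could raise the immediate early list. The test was chosen after vehicle mouse 2 had been seen to stand apart, so it does not decide the cause. Heat shock genes, which handling can also raise, were lower in vehicle mouse 2, at -0.24 against 0.29 and 0.38 in the other vehicle mice. That argues against a stress response that raises both lists. After removal of the trend on GC content and length 94.8% of the spread of its deviation was left, which argues against that trend as the cause. The 2 libraries with fewer counts, (R)-dHTC1 mouse 2 and (S)-dHTC1 mouse 3, deviated from the others of their groups with 43.1% and 55.7% of that spread, which argues against low depth as the cause. Vehicle mouse 1 thinned to the same depth deviated from vehicle mouse 3 with 39.9% of that spread, which decides nothing, since the thinning removed 3.84% of its counts. The labels give no difference between the vehicle mice that could be set against these.

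The fold changes of (R)-dHTC1 lay in the direction of (S)-dHTC1 in 294 of the 344 genes called for (S)-dHTC1 (85.5%), with a median of 0.221 in that direction. Over all genes the share was 66%. Simulated data in which (R)-dHTC1 did nothing gave 70.3% (66.8% to 73.1%) and a median of 0.0936 (0.0720 to 0.110). That simulation had 1109 genes called for (S)-dHTC1 on average, treats genes as independent, and has ranges too narrow to decide. With a different vehicle library for each enantiomer, the covariance of the fold changes ran from -0.0351 to 0.0468 and was above 0 in 4 of 6 choices. A weak shared effect and shared vehicle libraries cannot be told apart with 3 vehicle mice, and the covariance was negative where mouse 2 served (R)-dHTC1.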
